A study of Mus musculus with 12 samples.

How the data were processed

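RNA-seq was analysed in 12 libraries of mouse embryonic stem cells, in 6 groups of 2: Foxd3fl/fl;Cre-ER cells treated with 4-hydroxytamoxifen (2 µM, 3 days; called deleted) or untreated (called floxed), in SL (15% fetal bovine serum, leukemia inhibitory factor, irradiated fibroblast feeders) and in 2i (PD0325901 at 0.4 µM and CHIR99021 at 3 µM), and tetON Foxd3 and wild-type cells, both given doxycycline (1 µg/µl, 3 days) in serum without feeders. Per the labels' protocols, polyadenylated RNA was made into libraries with a TruSeq kit. The protocol for 2i names no feeders, so medium and feeders differ together. There was no group given tamoxifen without the floxed allele. The labels do not say whether the 2 replicates of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical. Which medium a deletion table belongs to was taken from the table's name, and each column was matched to a library by its own name.

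The authors deposited 1 table per comparison, of 19996 genes in SL and overexpression and 19718 in 2i. Per the file headers, each table gives FPKM (fragments scaled to transcript length and to library size) per library; these FPKM values are the unit of the tests here. Per the submitters' processing notes, the pipeline named FastQC, TopHat2, SAMtools, Cufflinks and DESeq2 and the builds GRCm38 and mm10; the versions are not given in the sources used here. Per the file headers, the authors also gave a mean read signal for each group, a signed fold change as a ratio of the groups and an unadjusted p-value. The mean read signal is a group mean after the authors' own scaling, so it carries no spread and gives no depth of a single library. The deposited p-value is rounded to 6 decimals, so small ones are listed as 0. Low-count folds in 2i were smaller than the ratio of the mean reads. Infinite folds numbered 0 in 2i, against 390 in SL and 363 in overexpression. The deposited test may therefore differ between 2i and the other comparisons, which limits counts and overlaps of the authors' calls set side by side. The 6 group average FPKM columns equal the mean of their libraries and were not used. Gene IDs were compared with GENCODE M21 (GRCm38), which held 19513 of the IDs of each table, and coordinates come from it.

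Count tests were not run, since FPKM is not a count: the design foresaw limma-trend for this unit. In each comparison the 4 libraries were fitted alone on log2(FPKM + 1), with genes of a mean of at least 1 FPKM in at least 1 group, moderated with limma 3.58.1 in R 4.3.3 (2 residual degrees of freedom) and adjusted by Benjamini and Hochberg, with a threshold of 0.05. A fold change on this scale understates the change of low genes. An exact permutation of 2 against 2 cannot give a 2-sided p below 0.3333 and was not used. An FPKM of 0 in a group with more than 200 mean reads was taken as a failed estimate, and such values are given as listed. The authors' p-values were adjusted here over all genes of a table as a second set of calls.

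The SL and 2i tables were fitted together for the test of the difference between media, which needs a shared normalization. For genes with more than 200 mean reads, a group's mean FPKM was divided by the gene's share of the authors' mean reads. Between groups of different tables, the median log2 ratio of this quantity was at most 0.154 in size. Its median absolute deviations were 0.0421 to 0.113 over 9227 to 10432 genes. FPKM levels themselves were not compared, so this does not show that they agree across tables. A factor common to a table cancels within its own contrast, but a factor between the groups of a table does not, and the test was also run after median-of-ratios scaling.

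Gene lists (26, fixed before the data were examined, with markers of other cell types among them) were tested with camera at a preset correlation of 0.01 where at least 5 members were tested, with an estimated correlation beside it, and with fry, which asks whether the genes of a list move one way on balance and does not compare the list with other genes. With an estimated correlation camera also refers its statistic to the 2 residual degrees of freedom, where a small p is hard to reach. A call lost there therefore does not show that correlation within the list produced it. Members are counted over all genes and adjusted over the list alone. The genes named were chosen by a rule fixed before the data were examined: Foxd3, the 10 largest rises and 10 largest falls past the threshold with both libraries of a group above both of the other and a mean of at least 1 FPKM over the 4 libraries, up to 4 members of each list by adjusted p, up to 10 genes called in opposite directions in deletion and overexpression, and up to 10 genes of the difference between media. Predicted genes, pseudogenes and rows that join several gene symbols were left out of the rises and falls. In SL this rule named Peg10 alone, and the same rule was then applied to the authors' table. A list of YAP and TEAD targets was added after the 2i genes had been seen.

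The tests were tried on simulated data with 100 genes changed by 2-fold and 100 by 4-fold. These genes were drawn from those well above the filter of 1 FPKM. In SL 77 and 99 of them were recovered over 11880 genes, and in 2i 99 and 100 over 11339. In overexpression 70 and 99 were recovered over 11766, and for the difference between media 78 and 98 over 11120, with 0 in the wrong direction. Unchanged genes called numbered 12 in SL, 7 in 2i, 11 in overexpression and 17 for the difference between media. The recoveries do not carry over to low genes, Foxd3 in SL among them, nor to data where fewer genes change. Replicates of a group correlated at 0.985 to 0.996, and the median SD of log2(FPKM + 1) was 0.0975 and 0.13 in SL deleted and floxed, 0.0525 and 0.0644 in 2i, and 0.107 and 0.11 in tetON Foxd3 and WT. Alternatives were no filter, a pseudocount of 0.1, a replicate block, a fold of at least 2, each library left out in turn, an estimated correlation, scaling and the authors' p. Tables were read with Python 3.11.15 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.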

Results

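Gene expression was measured by sequencing of polyadenylated RNA in 12 libraries of mouse embryonic stem cells, in 6 groups of 2. The series manipulated Foxd3, a forkhead transcription factor of pluripotent cells and of the neural crest. In Foxd3fl/fl;Cre-ER cells the floxed gene is removed by a recombinase that 4-hydroxytamoxifen activates. These cells were treated for 3 days or left untreated, in medium with serum and leukemia inhibitory factor (SL) on irradiated fibroblast feeders, or in medium with leukemia inhibitory factor and inhibitors of MEK and GSK3 (2i). In the third comparison a line carrying a doxycycline-inducible Foxd3 (tetON Foxd3) and wild-type cells (WT) both received doxycycline for 3 days in serum medium without feeders. The depth of each library is not known. The authors' group mean reads, which carry the authors' own scaling, summed to 53193800 and 54096100 in the SL deleted and floxed groups and to 52789800 and 52911400 in tetON Foxd3 and WT. In 2i they summed to 24278900 in the libraries labelled deleted and to 27062500 in the floxed ones. Between 11033 and 11919 genes per library reached 1 FPKM.

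Foxd3 itself was examined first, as a check of the labels. Foxd3 (ENSMUSG00000067261, chromosome 4, 99656299 to 99658622, plus strand, GRCm38) measured 1.72 ± 0.154 FPKM in the SL deleted libraries and 4.67 ± 0.200 FPKM in the SL floxed libraries (SD, n = 2 each). The log2 difference of -1.06 (SE 0.15) had an adjusted p of 0.137 in limma's test on FPKM, short of the threshold of 0.05. The authors' test, adjusted here, did not call Foxd3 in SL either (log2 fold -0.93, adjusted p = 0.16). With doxycycline, Foxd3 rose to 51.6 ± 2.18 FPKM in tetON Foxd3 against 12.3 ± 2.52 FPKM in WT (SD, n = 2 each; log2 difference 1.99, SE 0.15, limma adjusted p = 0.0145). In 2i, Foxd3 did not bear out the labels: it measured 2.26 ± 0.265 FPKM in the libraries labelled Foxd3-/- and 2.47 ± 0.0658 FPKM in the floxed ones (SD, n = 2 each). That log2 difference of -0.09 had a 95% interval from -0.33 to 0.15. After median-of-ratios scaling it was -0.25 (95% interval -0.48 to -0.02, limma adjusted p = 0.0595), and both intervals exclude the size of -1.06 seen in SL. The authors' deposited table listed Foxd3 at 376 mean reads against 221, a fold of 1.7 in favour of the libraries labelled deleted (adjusted p = 9.4e-06). The deleted segment is not given in the sources used here, so reads from outside it may count toward Foxd3. The 2i groups are therefore named by their labels throughout.

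**Figure D1:**
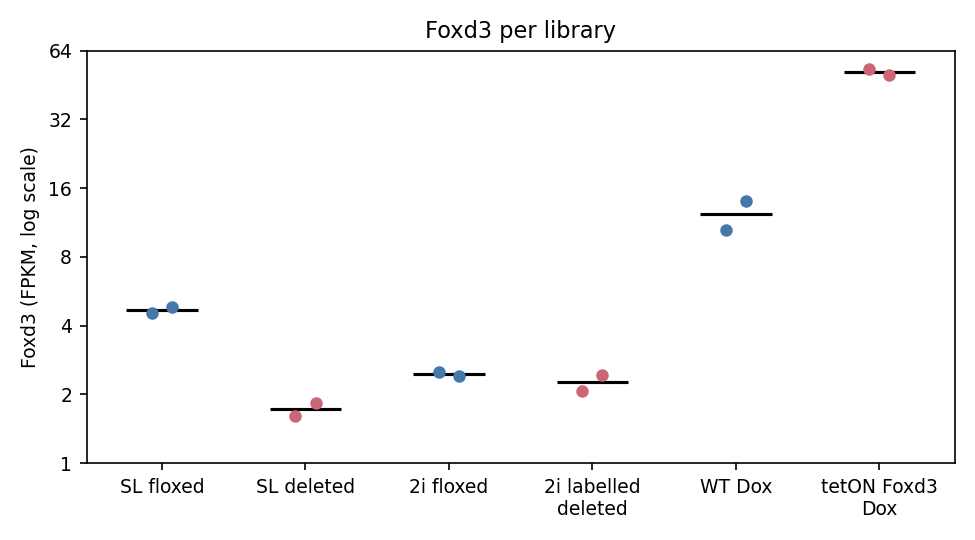
Foxd3 in FPKM (log scale) for each of the 12 libraries (points), with the mean of each group of 2 as a line. The SL deleted libraries lie at 1.62 and 1.83 FPKM, the 2i libraries of both groups between 2.07 and 2.51 FPKM, and the tetON Foxd3 libraries at 50.1 and 53.2 FPKM.

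The SL comparison asked how loss of Foxd3 changes gene expression in serum. By the camera test of fixed lists, genes of primordial germ cells, trophectoderm, the 2-cell-like state and fibroblasts stood higher in the deleted libraries and glycolysis genes lower. With an estimated correlation, tested on 2 degrees of freedom, these list calls were lost (adjusted p = 0.403 to 0.633). Of the members of these lists, 0 passed limma over all genes. Tfap2c, a transcription factor of primordial germ cells and trophoblast, measured 38.9 ± 8.62 FPKM in deleted and 10.97 ± 0.458 FPKM in floxed libraries (SD, n = 2 each). Htra1, a secreted serine protease, measured 20.4 ± 2.59 against 8.11 ± 0.0855 FPKM (SD, n = 2 each). Ldha, the lactate dehydrogenase subunit of glycolysis, measured 566 ± 27.2 FPKM in deleted and 778 ± 11.7 FPKM in floxed libraries (SD, n = 2 each). These 3 genes passed the authors' test in their deposited table, adjusted here, but not limma's test on FPKM (adjusted p = 0.0873 for Tfap2c and Htra1 and 0.185 for Ldha).

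Of 12024 genes tested with limma in SL, 1 was higher and 0 were lower at an adjusted p under 0.05, with 730 higher and 367 lower at an unadjusted p under 0.05. The single call was the imprinted gene Peg10, which was listed at 101.9 and 82.07 FPKM in the deleted libraries and at 0 in both floxed libraries. The authors' deposited table gives Peg10 20520 mean reads in the floxed group and a fold of 1.65 (adjusted p = 0.17), so the listed 0 is taken as a failed estimate. Without such genes 0 of 12020 passed limma's adjusted threshold, with 729 higher and 367 lower at an unadjusted p under 0.05. The p-values of the authors' deposited table, adjusted here over its genes, gave 88 genes higher and 19 lower. The limma count was 77 without deleted replicate 1, 308 without deleted replicate 2 and 12 without floxed replicate 2.

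The genes with the strongest changes in SL were taken from the authors' deposited table, a choice made after the FPKM test had named only Peg10. Rows of a single gene past the adjusted threshold were ranked, with predicted genes, such as 3830417A13Rik (3.61-fold), left out. A mean of at least 1 FPKM over the 4 libraries and no overlap between the groups were required. By that table, the largest rises were those of Prkch (7.11-fold), a protein kinase C, and Gcm1 (7.11-fold), a trophoblast transcription factor. Nrk (4.96-fold), Urgcp (4.21-fold), Rhox6 (4.11-fold), Limch1 (3.82-fold) and Tfap2c (3.6-fold) followed in the authors' deposited table. The iron exporter gene Slc40a1 (3.47-fold), Hand1 (3.46-fold), a transcription factor of trophoblast and mesoderm, and Zbtb10 (3.28-fold) rose as well by the authors' deposited table. Olig3, at 6.65-fold in the authors' deposited table and named after its values were seen, lay below that mean, with 1.74 and 1.16 FPKM in deleted and 0.309 and 0.232 FPKM in floxed libraries. Reads of the X-linked homeobox gene Rhox6 may be shared with its close relative Rhox9, which measured 11.8 ± 3.57 against 3.21 ± 1.25 FPKM (SD, n = 2 each). The largest falls in the authors' deposited table by the same limits were those of the mitochondrial protein gene Ndufa4l2 (-3.05-fold), the meiosis gene Stra8 (-2.7-fold), Ndrg2 (-2.44-fold) and the transcription factor gene Bcl11a (-2.41-fold). Calca (-2.35-fold), A2m (-2.21-fold), the imprinted gene Phlda2 (-1.99-fold), Dnah8 (-1.99-fold), Enpp2 (-1.98-fold) and Pgm2 (-1.76-fold) also fell by the authors' deposited table. In FPKM, Stra8 measured 2.56 ± 0.198 in deleted and 7.19 ± 0.451 in floxed libraries, and Phlda2 63.8 ± 2.77 against 124 ± 14.0 (SD, n = 2 each).

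Markers of another cell type moved with the deletion in SL. The fibroblast list stood higher in the deleted libraries (median log2 difference 0.55, camera adjusted p = 2e-17; adjusted p = 0.403 with an estimated correlation). Of its 22 tested members 0 passed limma over all genes and 17 were higher adjusted over the list alone. Of its genes, 6 rose by the authors' deposited table, adjusted here. The matrix proteoglycan Bgn measured 124.5 ± 10.7 against 74.6 ± 8.61 FPKM and the matricellular protein gene Thbs1 71.7 ± 4.29 against 44.2 ± 6.09 FPKM (SD, n = 2 each). Their folds in the authors' deposited table were 1.62 and 1.6. Collagen Col1a2, at 1.53-fold, and fibrillin Fbn1, at 1.76-fold, rose in the same table. The Y-linked gene Eif2s3y measured 1.14 and 0.931 FPKM in the deleted libraries and 0.578 and 0.637 FPKM in the floxed ones, and Ddx3y 0.444 and 0.5 against 0.324 and 0.285 FPKM. Both Y-linked genes were listed at 0 in every 2i, tetON Foxd3 and WT library.

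**Figure D2:**
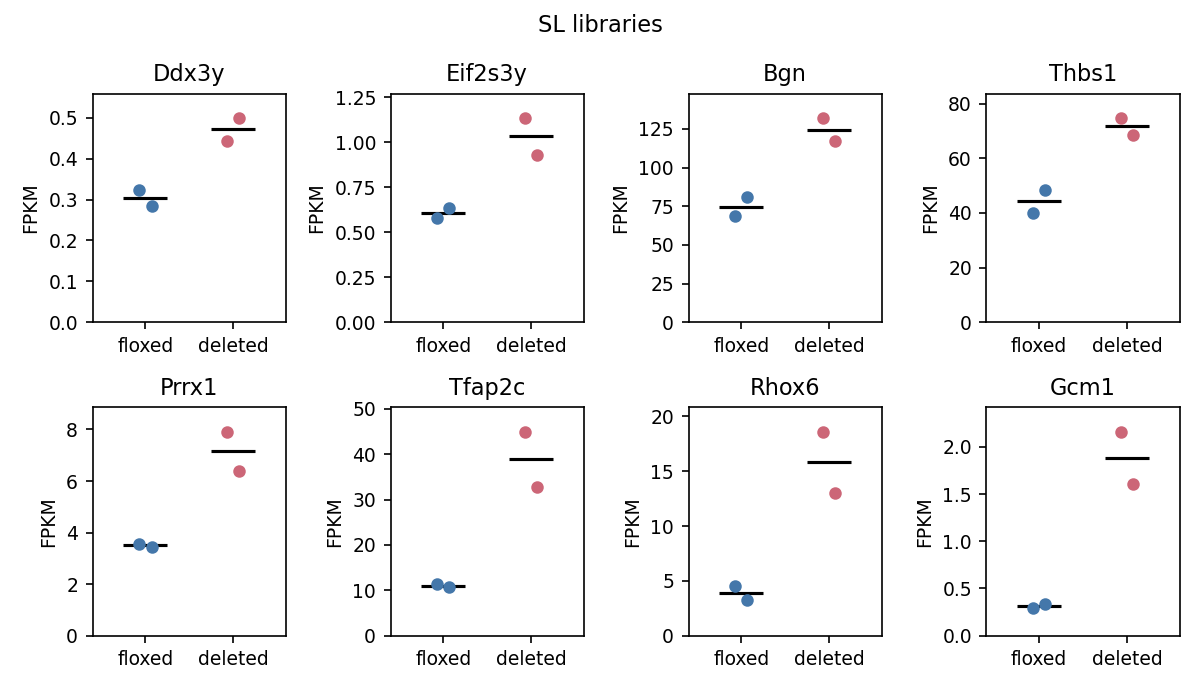
FPKM of 8 genes in the 4 SL libraries (points), with the mean of each group of 2 as a line and each axis starting at 0. The Y-linked genes Ddx3y and Eif2s3y and the fibroblast genes Bgn, Thbs1 and Prrx1 lie higher in the deleted libraries, as do Tfap2c (45.0 and 32.8 against 11.3 and 10.6 FPKM), Rhox6 and Gcm1.

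The list of primordial germ cell specification also stood higher in SL deleted libraries (median log2 difference 0.38, camera adjusted p = 1.06e-06; adjusted p = 0.403 with an estimated correlation), beside the fibroblast median of 0.55. Of its 12 members 0 passed limma over all genes, 4 were higher adjusted over the list alone, and Tfap2c rose by the authors' deposited table. Other members, with no call over all genes, were Nanos3, at 4.46 ± 2.16 against 0.502 ± 0.158 FPKM, Prdm14, at 5.24 ± 1.45 against 2.16 ± 0.193 FPKM, and Dppa3, at 103 ± 14.6 against 56.5 ± 18.0 FPKM (SD, n = 2 each). The 2-cell-like list, genes of the early embryo that a few stem cells express, had a median of 0.90 (camera adjusted p = 5.63e-12; adjusted p = 0.51 with an estimated correlation), and all 11 tested members were higher adjusted over the list alone, with 0 over all genes. Among them, Zscan4c measured 5.42 ± 1.92 against 1.86 ± 0.301 FPKM and Tcstv3 2.92 ± 1.16 against 0.613 ± 0.187 FPKM (SD, n = 2 each). Both belong to families of near-identical copies, and their levels are uncertain. The trophectoderm list had a median of 0.48 (camera adjusted p = 0.000223; adjusted p = 0.403 with an estimated correlation), with 3 of 7 members higher adjusted over the list alone, 0 over all genes, and Gcm1 higher in the authors' deposited table. Targets of p53 stood slightly higher (median 0.27, camera adjusted p = 8.58e-06; adjusted p = 0.403 with an estimated correlation), with 0 of 19 members passed over all genes or adjusted over the list alone. The fibroblast and Y-linked differences given above were measured in these same libraries.

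Naive pluripotency genes and the DNA methylation machinery were past the list threshold in SL with small medians. The naive list had a median of 0.16 (camera adjusted p = 0.0353; adjusted p = 0.74 with an estimated correlation), with 1 of 22 members higher adjusted over the list alone and 0 over all genes. Without deleted replicate 1 its direction turned (median -0.01, adjusted p = 0.475), and without floxed replicate 2 it did not pass (0.751). Tbx3, a transcription factor of the naive state, measured 13.1 ± 4.93 against 4.15 ± 1.06 FPKM (SD, n = 2 each). The DNA methylation list had a median of 0.09 (camera adjusted p = 0.0376; adjusted p = 0.51 with an estimated correlation), with 3 of 11 members higher adjusted over the list alone and 0 over all genes. Its members Gadd45a (1.71-fold) and Gadd45b (1.92-fold), known as DNA damage response genes, rose by the authors' deposited table. The formative and primed epiblast list was lower (median -0.33, camera adjusted p = 0.0233; adjusted p = 0.633 with an estimated correlation). Its 2 members past the test adjusted over the list alone were higher, and Fgf5, a growth factor of the primed epiblast, rose by 2.63-fold in the authors' deposited table. Glycolysis and hypoxia genes were lower (median -0.32, camera adjusted p = 1.06e-06; adjusted p = 0.633 with an estimated correlation), with 3 of 15 members lower adjusted over the list alone and 0 over all genes. Beside Ldha, Aldoa measured 893 ± 39.6 against 1132 ± 95.5 FPKM (SD, n = 2 each). The members of this list moved together, with an estimated correlation of 0.73. In overexpression, where the list was not called, its median of 0.05 became -0.47 without tetON Foxd3 replicate 1. A shift of the size seen in SL can therefore arise between replicates. The formative list did not pass without deleted replicate 1 (0.415) or floxed replicate 2 (0.108), nor the DNA methylation list without floxed replicate 1 (0.0933). In these libraries the fibroblast list stood 0.55 higher. The other 16 of the 25 lists tested had a camera adjusted p of 0.101 or more, among them core pluripotency, primitive and visceral endoderm, neural ectoderm, neural crest and gastrulation mesendoderm.

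**Figure D3:**
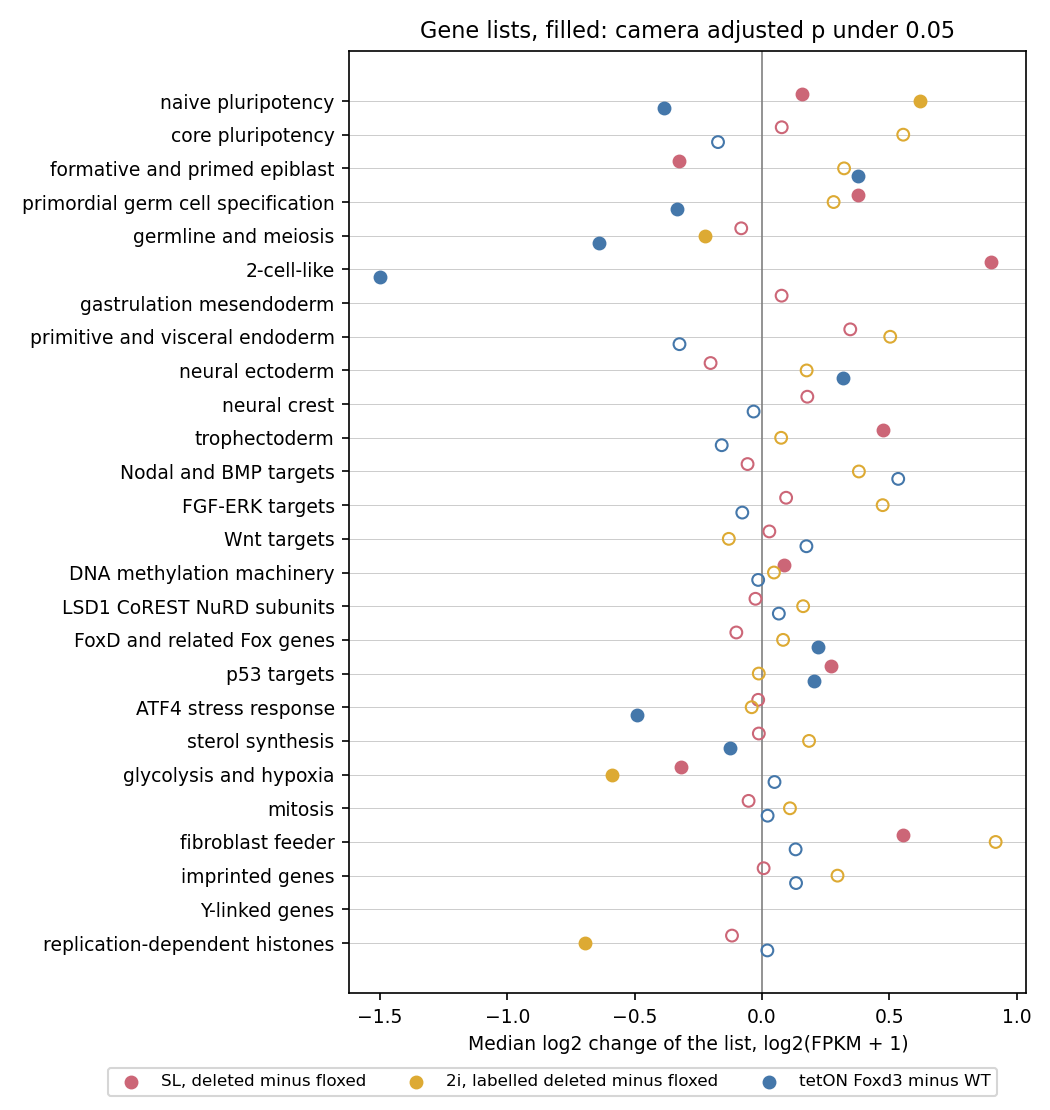
Median log2 difference, on the log2(FPKM + 1) scale, of each of 26 gene lists in the 3 comparisons (points; filled where the camera adjusted p was under 0.05, absent where fewer than 5 members were tested). The 2-cell-like list lies at 0.90 in SL and at -1.50 in tetON Foxd3, and the glycolysis list at -0.32 in SL and -0.59 in 2i.

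In 2i the same contrast was examined in cells held in the naive state by the inhibitors. In the libraries labelled Foxd3-/- (2i), 17 of 22 naive pluripotency genes were higher, and 14 of 16 glycolysis and hypoxia genes, 12 of 26 germline genes and all 9 replication-dependent histones tested were lower. With an estimated correlation, tested on 2 degrees of freedom, these 4 list calls were lost (adjusted p = 0.889), and 6 germline genes were higher. The germline list also did not pass after median-of-ratios scaling (camera adjusted p = 0.0652). The naive factor Nanog rose to 280.0 ± 9.47 FPKM against 144 ± 2.10 FPKM in the floxed libraries (SD, n = 2 each; log2 difference 0.95, SE 0.05), and Tbx3 to 42.7 ± 2.03 against 12.8 ± 1.21 FPKM (SD, n = 2 each). Cyr61 and Ctgf, secreted matrix proteins, rose to 53.4 ± 3.36 against 5.08 ± 0.783 FPKM and to 27.9 ± 1.54 against 2.97 ± 0.397 FPKM, and Ldha fell to 356 ± 34.1 against 646 ± 32.9 FPKM (SD, n = 2 each). All of these passed limma's test, with adjusted p-values of at most 2.81e-05. Foxd3 did not pass as lower in these libraries, so the directions follow the labels only.

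Of 11637 genes tested with limma in 2i, 5573 were higher and 2291 lower in the libraries labelled deleted. With median-of-ratios scaling of the FPKM the split became 3509 higher and 3921 lower, and the authors' deposited p-values, adjusted here, gave 4071 higher and 3980 lower. The median log2 difference of all tested genes was 0.19 in the FPKM as deposited and -0.02 after scaling, so a gene at 0.19 stood at the median. With a fold of at least 2 required, 776 genes passed, Nanog and Ldha not among them.

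The largest rises in 2i relative to that shift were those of Aspa, an aspartoacylase, at 11.6 ± 0.506 against 0.399 ± 0.0564 FPKM, Cyr61, the small GTPase gene Rhob, at 18.2 ± 2.93 against 1.6 ± 0.213 FPKM, and Ctgf (SD, n = 2 each). Htra1 followed at 40.3 ± 0.325 against 5.44 ± 0.676 FPKM (SD, n = 2 each). Wdr45, the stem cell antigen gene Ly6a, Msc and Fgfbp1 completed the rises named by the fixed rule, with log2 differences of 2.63, 2.56, 2.50 and 2.49. The rule also named Txnrd3 among the rises and Ept1 among the falls, but the authors' mean reads do not bear these out: the authors' deposited table lists folds of 1.1 and 1.26, so both are uncertain. The largest falls were those of Rasd1, a Ras-related GTPase, at 1.2 ± 0.0791 against 24.9 ± 1.73 FPKM, the stress gene Gadd45g, at 10.5 ± 1.31 against 109 ± 25.8 FPKM, and Igfbp4, at 2.53 ± 0.137 against 29.4 ± 1.16 FPKM (SD, n = 2 each). Klk1, Ndufa4l2, Calb2, Gpx6, the Notch ligand Dll1 and Abcg1 fell by 2.82, 2.71, 2.67, 2.66, 2.64 and 2.49 on the log2 scale.

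Among the lists in 2i, naive pluripotency was higher (median log2 difference 0.62, camera adjusted p = 0.00662; adjusted p = 0.889 with an estimated correlation), with 17 of 22 members higher, 3 lower and 2 not passed. There were 16 higher and 3 lower after scaling. The counts adjusted over the list alone were also 17 and 3. Fbxo15 rose to 170 ± 6.33 against 75.8 ± 2.96 FPKM and the imprint regulator Zfp57 to 267 ± 3.47 against 140 ± 0.407 FPKM (SD, n = 2 each). Glycolysis and hypoxia genes were lower (median -0.59, camera adjusted p = 2.44e-08; adjusted p = 0.889 with an estimated correlation). Of 16 members 1 rose and 14 fell, over all genes and adjusted over the list alone, and after scaling 0 rose and 15 fell. Examples beside Ldha were the hypoxia-induced peptide gene Adm, at 0.734 ± 0.26 against 6.96 ± 0.202 FPKM, Ndrg1, at 13.8 ± 0.768 against 34.8 ± 0.648 FPKM, and the collagen hydroxylase gene P4ha1, at 37.6 ± 1.72 against 74.1 ± 0.317 FPKM (SD, n = 2 each). All 9 tested replication-dependent histone genes were lower, also adjusted over the list alone (median -0.69, camera adjusted p = 6.69e-05; adjusted p = 0.889 with an estimated correlation). They share reads between near-identical copies, and their estimated correlation was 0.84, so they are not 9 separate observations. By the authors' p, adjusted here, 5 of the 12 members in the deposited table were lower and 0 higher. Of 26 germline and meiosis genes 6 rose and 12 fell, over all genes and adjusted over the list alone (median -0.23, camera adjusted p = 0.00662; adjusted p = 0.889 with an estimated correlation). After scaling the camera adjusted p was 0.0652. Sohlh2 fell to 13.4 ± 0.723 against 29.7 ± 1.63 FPKM and Fkbp6 to 22.5 ± 0.424 against 45.2 ± 2.19 FPKM, while Rhox6 rose to 59.4 ± 0.132 against 35.3 ± 2.27 FPKM (SD, n = 2 each).

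The remaining 18 of 22 lists tested in 2i had a camera adjusted p of 0.352 or more. Of 12 core pluripotency genes 8 rose and 1 fell, with 6 and 3 after scaling. Dppa2 rose to 18.5 ± 2.44 against 5.5 ± 0.138 FPKM, and Lin28a, an RNA-binding protein gene, fell to 19.8 ± 1.68 against 51.7 ± 0.25 FPKM (SD, n = 2 each). Among Nodal and BMP targets 8 of 12 rose, 0 fell and 4 did not pass, with 5 higher and 1 lower after scaling. Id2 rose to 41.2 ± 0.776 against 8.19 ± 0.53 FPKM (SD, n = 2 each). Of 12 primordial germ cell genes 7 rose and 5 fell, with Tfap2c at 59.4 ± 5.72 against 31.4 ± 0.653 FPKM and Pdpn at 14.3 ± 2.35 against 61.8 ± 7.80 FPKM (SD, n = 2 each). Fibroblast genes were low in 2i: their summed FPKM averaged 62.1 over the 4 libraries, against 578 in SL. Of the 9 fibroblast genes tested 6 rose and 2 fell. For several of these lists the camera direction, which is relative to all other genes, was down although the median was positive. The 2-cell-like, gastrulation mesendoderm, neural crest and Y-linked lists had fewer than 5 members at 1 FPKM and were not tested.

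The overexpression comparison asked what a gain of Foxd3 changes in serum. By the camera test, the lists of naive pluripotency, germline and 2-cell-like genes stood lower in tetON Foxd3 and those of formative epiblast and neural ectoderm higher. With an estimated correlation, tested on 2 degrees of freedom, these list calls were lost (adjusted p = 0.669 to 0.691). Single calls were 5 of 22 naive, 4 of 27 germline and 6 of 8 2-cell-like genes lower, and 1 of 17 formative and 2 of 7 neural ectoderm genes higher. Dppa5a, a marker of undifferentiated cells, fell to 512 ± 71.1 against 1318 ± 93.3 FPKM in WT (SD, n = 2 each; log2 difference -1.37, SE 0.12), and the germ cell gene Dppa3 to 2.02 ± 0.00281 against 10.7 ± 1.09 FPKM (SD, n = 2 each). The neural progenitor filament gene Nes rose to 7.09 ± 1.87 against 1.34 ± 0.318 FPKM, and Id2, an inhibitor of basic helix-loop-helix factors, to 61.2 ± 1.62 against 15.5 ± 3.07 FPKM (SD, n = 2 each). These genes passed limma's test, with adjusted p-values from 0.0145 to 0.0298.

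Of 11972 genes tested with limma, 119 were higher and 197 lower in tetON Foxd3, with 1245 and 1241 at an unadjusted p under 0.05. The authors' deposited p-values, adjusted here, gave 392 higher and 517 lower. With no filter on low values 0 of 17032 genes passed limma's adjusted threshold, with 1608 higher and 1624 lower at an unadjusted p under 0.05. The count was 143 without tetON Foxd3 replicate 1, 39 without WT replicate 1 and 97 without WT replicate 2. The groups are different lines, so line and transgene are not separated.

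The rises named by the fixed rule were, beside Foxd3, Nes and Id2, those of the Wnt antagonist gene Sfrp2, at 40.6 ± 18.4 against 6.27 ± 1.20 FPKM, and Cd24a, at 49.6 ± 0.587 against 9.92 ± 1.44 FPKM (SD, n = 2 each). They were followed by Kcnj3, at 6.77 ± 2.83 against 0.613 ± 0.0248 FPKM, and Foxi3, another forkhead gene, at 5.37 ± 0.571 against 0.583 ± 0.193 FPKM (SD, n = 2 each). Coch, Colec12 and Cdk5r2 completed them with log2 differences of 2.00, 1.85 and 1.76. Of the 10 largest falls, 7 belonged to the X-linked lymphocyte-regulated family, with Xlr5a at 2.64 ± 0.318 against 51.6 ± 4.66 FPKM and Xlr3b at 2.22 ± 0.405 against 36.0 ± 8.98 FPKM (SD, n = 2 each). The 9 tested Xlr3, Xlr4 and Xlr5 genes lie at 73074345 to 73292976 on the X chromosome (GRCm38) and all fell, by 2.90 to 3.86 on the log2 scale. They are near-identical copies, and the share of each is uncertain. The other 3 of these falls were those of Msln, at 4.09 ± 3.07 against 37.4 ± 5.34 FPKM, Htra1, at 3.6 ± 2.08 against 35.2 ± 4.46 FPKM, and the oocyte gene Khdc3, at 1.08 ± 0.615 against 15.2 ± 3.51 FPKM (SD, n = 2 each).

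Lower lists in tetON Foxd3 were led by the 2-cell-like genes (median log2 difference -1.50, camera adjusted p = 9.32e-09; adjusted p = 0.669 with an estimated correlation). Of 8 tested, 6 fell and 2 did not pass, and all 8 were lower adjusted over the list alone. Zscan4c fell to 0.491 ± 0.00287 against 3.98 ± 0.695 FPKM (SD, n = 2 each). Of 22 naive pluripotency genes 0 rose, 5 fell and 17 did not pass, with 9 lower adjusted over the list alone (median -0.38, camera adjusted p = 2.81e-05; adjusted p = 0.669 with an estimated correlation). Ooep fell to 11.5 ± 0.647 against 45.5 ± 10.1 FPKM and Tbx3 to 18.5 ± 0.0490 against 39.0 ± 0.0820 FPKM (SD, n = 2 each). Of 27 germline genes 1 rose, 4 fell and 22 did not pass, with 1 and 9 adjusted over the list alone (median -0.64, camera adjusted p = 1.63e-06; adjusted p = 0.691 with an estimated correlation). Rhox5 fell to 38.0 ± 3.49 against 108 ± 10.5 FPKM (SD, n = 2 each). Primordial germ cell genes had 2 of 12 lower, and 3 adjusted over the list alone (median -0.33, camera adjusted p = 0.0118; adjusted p = 0.669 with an estimated correlation). The ATF4 stress response had 2 of 13 lower, 4 adjusted over the list alone (median -0.49, camera adjusted p = 0.00154; adjusted p = 0.691 with an estimated correlation), with the asparagine synthetase gene Asns at 145 ± 17.7 against 287 ± 6.03 FPKM (SD, n = 2 each). Sterol synthesis genes were slightly lower (median -0.13, camera adjusted p = 0.0275; adjusted p = 0.691 with an estimated correlation), with 0 of 18 passed over all genes or adjusted over the list alone. Without WT replicate 1 the primordial germ cell list (adjusted p = 0.0724) and the sterol list (0.715) did not pass, nor did the former without tetON Foxd3 replicate 2 (0.0609), the latter without tetON Foxd3 replicate 1 (0.105) or the ATF4 list without WT replicate 2 (0.0805).

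Higher lists in tetON Foxd3 were fewer. The formative and primed epiblast list had a median of 0.38 (camera adjusted p = 0.00154; adjusted p = 0.691 with an estimated correlation), with 1 of 17 members higher and 1 lower, and 7 higher and 1 lower adjusted over the list alone. The transcription factor Sox4 rose to 8.63 ± 0.579 against 1.96 ± 0.546 FPKM, and Etv4, a target of FGF signalling, fell to 20.5 ± 1.53 against 69.8 ± 3.84 FPKM (SD, n = 2 each). Neural ectoderm genes had 2 of 7 higher, Nes and Sox1 (5.38 ± 0.103 against 2.18 ± 0.188 FPKM, SD, n = 2 each), and 3 adjusted over the list alone (median 0.32, camera adjusted p = 0.0388; adjusted p = 0.691 with an estimated correlation). FoxD and related Fox genes, with Foxi3 the member that rose among 7 (2 adjusted over the list alone), had a median of 0.22 (camera adjusted p = 0.0235; adjusted p = 0.669 with an estimated correlation). Targets of p53 had 0 of 18 passed over all genes, 5 higher adjusted over the list alone, and a median of 0.21 (camera adjusted p = 0.0195; adjusted p = 0.691 with an estimated correlation). The neural ectoderm, Fox and p53 lists did not pass without WT replicate 1 (adjusted p = 0.342, 0.0807 and 0.0657) or without tetON Foxd3 replicate 2 (0.121, 0.0609 and 0.121). The other 14 of 24 lists tested had a camera adjusted p of 0.0568 or more. In such lists, 3 of 12 core pluripotency genes fell, among them Dppa2 (16.6 ± 2.77 against 43.5 ± 1.76 FPKM, SD, n = 2 each). The de novo methylation cofactor Dnmt3l (57.2 ± 5.09 against 132 ± 29.2 FPKM, SD, n = 2 each) and the trophoblast factor Tead4 (3.15 ± 0.196 against 10.4 ± 3.19 FPKM, SD, n = 2 each) fell as well. The gastrulation mesendoderm and Y-linked lists were not tested.

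Deletion and overexpression in serum were then set against each other, to ask whether loss and gain of Foxd3 move genes in opposite directions. Across 11390 genes tested in both, the log2 differences had a Pearson r of -0.30 and a Spearman rho of -0.20. Genes are not independent replicates, so no p-value is attached to the correlation. The FPKM test called 0 genes in both. By the authors' deposited tables, adjusted here, 19 of 16480 genes were called in both and 17 of them in opposite directions, against 3.20 if the calls were independent. Of these, 15 rose after deletion and fell with overexpression (1-sided Fisher's exact test across genes, p = 8.19e-08), and 2 fell after deletion and rose with overexpression (p = 0.074 in the same exact test). These p-values treat genes as independent, which they are not. They were led by Baz1a (2.19 and -3.05-fold), the collagen receptor gene Ddr2 (2.87 and -4.76-fold), Dysf (2.37 and -3.73-fold) and Htra1 (2.71 and -10.75-fold) in the authors' deposited tables. The kinase gene Pim2 (-1.53 and 1.95-fold) and Bcl11a (-2.41 and 5.31-fold) moved the other way in those tables. The predicted gene Gm13119 (5.24 and -67.57-fold), Nup62cl (1.89 and -4.35-fold), the folate receptor gene Folr1 (2.35 and -2.63-fold) and Tfap2c (3.6 and -2.14-fold) completed the 10 named from the authors' deposited tables. Ddr2 is also a fibroblast gene, and fibroblast and Y-linked genes stood higher in the SL deleted libraries, as given above. Ddr2 was, however, also 1.6-fold higher in the authors' deposited table for 2i, whose protocol names no feeders, and its fall with overexpression was measured without feeders.

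**Figure D4:**
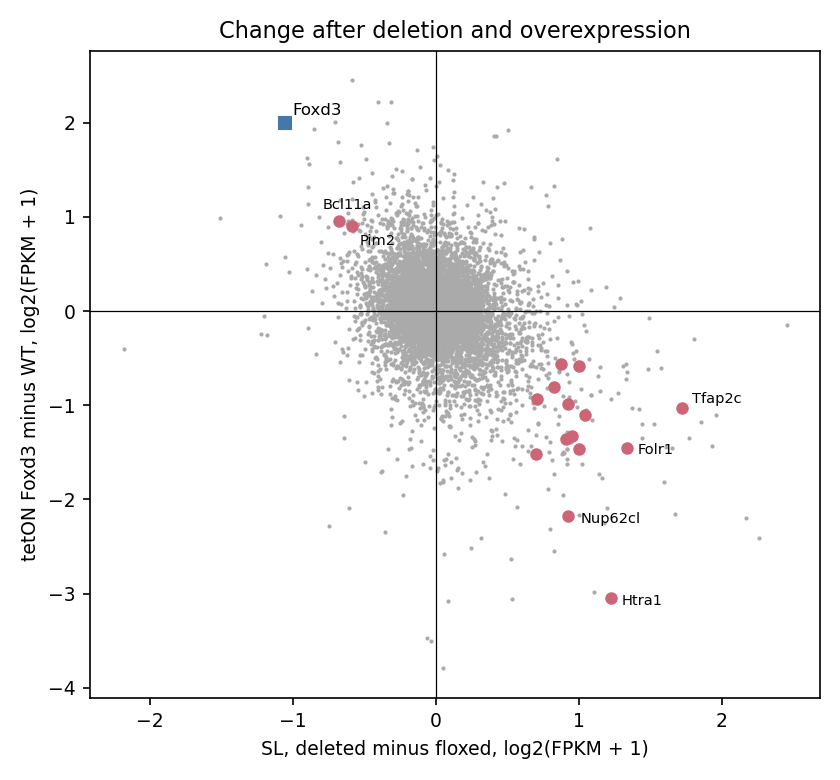
Log2 difference on the log2(FPKM + 1) scale after deletion in SL (x axis) and with overexpression (y axis), 1 grey point per gene tested in both and Peg10 left out. Red points are genes called in opposite directions in the authors' deposited tables that were tested here, and Foxd3 (blue square) lies at -1.06 and 1.99.

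The contrast of libraries labelled deleted and floxed was compared between the media, which differ in feeders as well as inhibitors. Across 11130 genes tested in both, the log2 differences in SL and 2i had a Pearson r of 0.34 and a Spearman rho of 0.33. The FPKM test called 1 gene in both, Peg10. By the authors' deposited tables, adjusted here, 80 of 16270 genes were called in both, and 74 of them moved the same way, against 26.6 if the calls were independent. These were 56 genes higher in both (1-sided Fisher's exact test across genes, p = 1.90e-14) and 18 lower in both (1-sided Fisher's exact test across genes, p = 1.37e-10), again with genes treated as independent. The other 6 were higher in SL and lower in 2i. Of the 17 genes that moved opposite ways with deletion and overexpression in SL, 14 were called in 2i and 13 of these moved as in SL.

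The test of the difference itself called 2987 of 12497 genes, 2294 with a difference, 2i minus SL, above 0 and 693 with one below 0, or 1226 and 1452 after median-of-ratios scaling. The 10 genes with the smallest adjusted p included Peg10, whose SL floxed values are listed at 0. The others were Ctgf, with a log2 change of 0.23 in SL and 2.86 in 2i, Cyr61 (0.38 and 3.17), the LIM protein gene Ajuba (-0.15 and 2.00), Rhob (-0.19 and 2.88) and Esr1 (-0.54 and 1.74). Rasd1 (0.46 and -3.56), Gadd45g (0.85 and -3.24) and the retinoic acid binding protein genes Crabp2 (-0.26 and -2.21) and Crabp1 (-0.22 and -1.84) had lower values in 2i. Their limma adjusted p-values were at most 0.000854, and at most 0.000594 after scaling. The number of genes called was 1951 without SL deleted replicate 1, and 1110, 682, 1729 and 898 without each of the 2i libraries (deleted replicates 1 and 2, floxed replicates 1 and 2).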

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

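The tests of explanations in this part were all chosen after the results were seen; the test of the difference between media was planned.

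The change between libraries labelled deleted and floxed differed between SL and 2i for 2987 genes. The difference of the log2 changes, 2i minus SL, was 2.64 for Ctgf, 2.79 for Cyr61, 2.16 for Ajuba, 3.07 for Rhob and 2.28 for Esr1. It was -4.02 for Rasd1, -4.08 for Gadd45g, -1.96 for Crabp2 and -1.61 for Crabp1. For Peg10 it was -5.46, which rests on SL floxed values listed at 0. Among the other genes named in both media, those past the threshold were Foxd3 itself (0.97), Htra1 (1.46), Ndufa4l2 (-1.21), Rhox6 (-1.04), Tfap2c (-0.82) and Ldha (-0.40). Tbx3 (0.24, limma adjusted p = 0.604) did not pass. The FPKM of the 2i libraries labelled deleted carry a median shift of 0.19, so differences of that size depend on the scaling.

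Foxd3 did not pass as lower in the 2i libraries labelled deleted (log2 change -0.09, or -0.25 after scaling), which bears on the labels and on the deletion in these cultures. A swap of the 2i labels would turn the shared changes around, yet 74 of the 80 genes called in both media by the authors' p moved the same way, which argues against it unless the deletion acts in opposite directions in the media. Whether Foxd3 was lost in 2i stays open: of the genes that moved opposite ways in SL deletion and overexpression, 13 of the 14 called in 2i moved as in SL, but so did 74 of all 80. Between 2i and overexpression, 284 of the 502 genes called in both by the authors' p moved opposite ways, against 224.9 if independent, 193 of them higher in 2i (1-sided Fisher's exact test, genes treated as independent, p = 2.17e-10) and 91 lower (p = 0.721), but Pearson's r over all genes was -0.04, so this does not settle it. An effect of tamoxifen, given in both media with no tamoxifen-only group, cannot be told apart from a loss of Foxd3, and the cultures may differ in other ways: Esr1, whose reads the Cre-ER construct could give, changed by 2.28 more in 2i, but it was picked for that difference and did not pass in SL.

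Genes that rose in SL rose together with fibroblast genes. Reads of the Y-linked genes listed at 0 in the other tables were 1.89 times as high in the deleted group. A larger share of RNA from the feeders would give this, if the stem cells lack a Y chromosome. Fibroblast genes also moved in 2i, whose protocol names no feeders: 10 rose and 3 fell by the authors' p, adjusted here. Thbs1, Col5a1 and Col1a2 rose in both media by that p, while Bgn, Fbn1 and Prrx1 did not pass in 2i. Feeder RNA therefore need not account for all of the fibroblast rise in SL. A larger feeder share could raise a gene by no more than the feeder share itself rose, taken here from the highest Y-linked fold of the authors, 2.65 for Kdm5d. Kdm5d had 26.6 and 10.05 mean reads in SL, and also 19.7 and 13.4 in 2i; by Eif2s3y (2.27), at 0 in the other tables, 30 genes would exceed the bound. Of the 88 genes higher by the authors' p, 23 exceeded the bound of 2.65 in fold and in every deleted over every floxed library. Among them were Tfap2c, Gcm1, Hand1, Nrk and Rhox6, and for these 23 the feeder share alone is argued against. In 2i 13 of the 23 were also higher and 0 lower. Of all 88, 56 were higher in 2i and 6 lower, so agreement with 2i does not set the 23 apart. For the other 65, feeder RNA and an effect of the deletion cannot be told apart, since both move with the treatment. Loss of Foxd3 remains, as a hypothesis, an explanation of the 23, beside an effect of tamoxifen that was not tested.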

How the results depend on the processing

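The scaling, the authors' p, leaving out genes listed at 0, the pseudocount of the difference between media and the correlations with a library left out were chosen after the data were seen; the other alternatives were planned. The cause of a change was not tested unless stated. The DESeq2 size factors, the DESeq2 test and calls and the fit of all 12 libraries need counts and were not run.

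With 1 library left out, and the lone sample assumed to vary like the other group, the count ranged from 1 to 308 in SL, from 6499 to 7787 in 2i, from 39 to 366 in overexpression and from 682 to 3744 for the difference between media. A fold of at least 2 left 776 genes in 2i and 207 in overexpression. With no filter overexpression gave 0 genes, as the smallest adjusted p of its 17032 genes was 0.0558, that of Foxd3 (log2 change 1.99). By the authors' p there were 107 genes in SL and 909 in overexpression, with 19 called in both. SL and 2i shared 80, by deposited tests that may not have been run alike. Without genes listed at 0, SL had 0 genes in limma's test, with 729 and 367 at an unadjusted p under 0.05. Scaling of the FPKM changed the 2i split from 70.87% to 47.23% higher, but this scaling centres the median by construction, so the source of the excess of rises stays open.

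The log2 change of Foxd3 ranged from -1.12 to -1 in SL with 1 library left out and passed the test without deleted replicate 1 (adjusted p = 0.0439) and without deleted replicate 2 (0.00426); over all alternatives its adjusted p reached 0.364, with no filter. The correlation of SL deletion with overexpression ranged from -0.34 to -0.18 with a library left out, and that of SL with 2i from 0.28 to 0.35. With an estimated correlation 0 lists passed in any comparison, and fry called 0 lists in SL, 5 in 2i and 1 in overexpression. The loss of calls with an estimated correlation partly reflects its 2 degrees of freedom. The trophectoderm list in SL had an estimated correlation of -0.098, below the preset of 0.01, yet its unadjusted camera p rose from 5.36e-05 to 0.0532. Other called lists lay far above the preset: 2-cell-like (0.68), glycolysis (0.73) and fibroblast (0.28) in SL, and glycolysis (0.58) and histones (0.84) in 2i. For these, camera p-values at the preset may be far too small. The primordial germ cell (0.041) and p53 (0.025) lists in SL lay nearer the preset. Of single lists, naive pluripotency in SL ranged in median from -0.013 (without deleted replicate 1, reversed) to 0.38, and glycolysis in overexpression, not called, from -0.47 (without tetON Foxd3 replicate 1, reversed and past the threshold) to 0.66 (without tetON Foxd3 replicate 2, also past it). The 42 genes named in 2i beside Foxd3 and the 10 of the difference between media kept direction and call with scaling, no filter, a pseudocount of 0.1, the replicate block and each library left out. A fold of at least 2 ended 7 of the calls in 2i and 2 in overexpression. By the authors' p Txnrd3 lost its call in 2i (log2 change 0.14) and Ept1 turned to 0.33, as did Foxd3 to 0.77. All 34 called in overexpression lost the call with no filter, and with a library left out 41 of their fits lost it and 95 kept it.

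The labels give the groups shared replicate numbers but no pairing. Same-numbered libraries deviated together with a correlation of 0.60 in SL, -0.05 in 2i and 0.60 in overexpression. A replicate block gave 1997 genes in SL, 2473 in overexpression, 5342 for the difference between media and 7566 in 2i, and a log2 change of Foxd3 in SL of -1.06 (adjusted p = 1.15e-16, on a spread pooled over all genes). Depth per library is not known, since FPKM and group means carry none.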

Other observations

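The tests of explanations in this part were all chosen after the results were seen, and the YAP and TEAD list was chosen after the 2i genes were.

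Ctgf, Cyr61 and Ajuba, genes known to respond to the coactivator YAP, were among the strongest differences between the media. A list of 20 further YAP and TEAD targets, 2 of which are also in the fixed lists, was tested to ask whether others moved with them. In the libraries labelled Foxd3-/- (2i), 8 of 13 tested members rose, 2 fell and 3 did not pass, also after scaling, with a median log2 difference of 0.64 (0.44 after scaling). Limma's camera test against all other genes gave an adjusted p of 0.371 over the 3 comparisons, so the test leaves open whether these targets may have risen as a group. In SL the list had a median of 0.46 (camera adjusted p = 2.11e-08; adjusted p = 0.166 with an estimated correlation) with 0 of 18 members passed by limma, in libraries where the fibroblast genes also stood higher. In overexpression camera gave an adjusted p of 0.794.

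The X-linked Xlr3, Xlr4 and Xlr5 genes fell together in tetON Foxd3, all 9 of those tested. A loss or silencing of the whole region in this line may have done this and would lower the neighbouring genes too. The 28 other genes tested within 1 Mb had a median log2 change of -0.075, with 2 of them lower and the lowest at -1.09. This argues against a loss of the whole region. Among the 28, F8a, which lies between Xlr genes, stood at -0.11 (limma adjusted p = 0.735), so a change of the cluster as 1 block would have to spare it. Directly before the cluster, Pnma5 (-0.77, limma adjusted p = 0.027) and Pnma3 (-0.67, limma adjusted p = 0.0845) stood lower, though by less than any Xlr gene. Zfp275, next after it, stood at 0.14 (limma adjusted p = 0.539). A change reaching a short way past the cluster is therefore not excluded. A change of the Xlr genes themselves in this line, unrelated to Foxd3, stays open, since the comparison holds a single tetON line.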
